A study of Homo sapiens with 3 samples.

How the data were processed

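RNA sequencing libraries were made from total RNA of the QBC-939 cholangiocarcinoma cell line, 1 library for each of 3 groups: cells overexpressing miR-182-5p, miR-183-5p or a control labelled NC. Per the labels, total RNA was extracted with Trizol. The submitters' processing notes name cutadapt 1.9 for trimming and FastQC for quality checks, and give the genome build as GRCm38, a mouse assembly, although all 30923 gene identifiers in the file are human Ensembl identifiers. The aligner, the counting program, its handling of strand and overlapping genes, and the annotation release are not given in the sources used here. The gene counts were made by the authors from the aligned reads and are whole numbers as deposited. The FPKM values (fragments counted relative to transcript length and library size) were deposited beside the counts, per the file headers, which do not say how they were computed. For the 14623 genes with at least 50 counts in each library, the deposited FPKM and the CPM (counts scaled to the library total) gave the same log2 difference between libraries apart from a constant, with an SD of 0.0052 across genes.

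Differences were computed as log2 of (FPKM + 1) in one library over (FPKM + 1) in the other, for genes with an FPKM of at least 1 in at least 1 of the 2 libraries. A gene was called different at 2-fold or more on this scale. This is a rule of size, since 1 library per group allows no test between conditions. The fixed design assumed a file of FPKM alone and said that single named genes would be given as CPM should counts be present, so ratios of single genes are CPM ratios. Their 95% intervals are exact (Clopper-Pearson, conditional on the sum of both counts) and cover counting error only. A fold against a count of 0 was computed against a floor of 3 counts, the 95% upper limit (1-sided) that a count of 0 allows, and is given as "at least"; this floor is lower than the 2-sided limit of the intervals. At the median gene length, 1 count in the NC library is an FPKM of 0.0039.

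Gene lists, the rule for naming genes, the thresholds and a set of other settings were written before the data were examined. The rule names, for each microRNA against NC, the 12 genes with the largest difference in each direction among genes with a symbol and at least 5 CPM in at least 1 of the 2 libraries, and the 6 largest in each direction between the microRNAs. It adds HPGD, the measured reported targets and prostaglandin genes, up to 2 members of each other list in each direction, and the 10 lowest genes with a seed site. Largest differences among genes that overlap no other gene on the same strand were added after the values were seen, as was a list of 30 NRF2-regulated genes. The 26 fixed lists cover reported targets of miR-182-5p and of miR-183-5p, prostaglandin genes, stemness and drug efflux, the epithelial-mesenchymal transition, cell cycle, FOXO-activated genes, interferon response, unfolded protein and integrated stress, cholesterol, hypoxia, p53, NF-kB, immediate early, Wnt feedback, TGF-beta, YAP and TAZ, glycolysis, microRNA machinery, biliary, hepatocyte, fibroblast, and immune or endothelial markers, mitochondrially encoded, ribosomal protein and histone genes. Each list with at least 3 measured members was given by its median log2 difference and by the percentile of that median among 10000 random lists of the same size matched on mean expression (20 bins). Genes are not replicates, so a percentile describes these libraries alone. The lower threshold was the 2.5th percentile and the upper threshold its mirror.

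Seed sites were searched in the longest annotated 3' UTR per gene in the human genome GRCh38 with the basic transcripts of GENCODE release 29, which holds 97.3% of the gene identifiers in the file. A site is the 7 nucleotides complementary to microRNA positions 2 to 8. Site genes among the 10553 genes searched were compared with genes lacking the 6-nucleotide site (positions 2 to 7), and with 10000 random lists matched on expression (10 bins) and 3' UTR length (5 bins). All heptamers found in at least 50 genes were ranked by the standardised mean difference of the genes that hold them. Sites of miR-96-5p, miR-21-5p, let-7a-5p and miR-16-5p served as comparisons. Genes were called overlapping when the span of another gene in the file covers part of theirs on the same strand. Overlap with genes on the opposite strand was looked up for named genes only, after the values were seen. The shared control was modelled by 100 simulations in which the 3 libraries have independent differences of equal spread. The SDs of the 3 comparisons, given below, were unequal and depart from this assumption.

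The procedure was tested on simulated data built from the NC library, with independent noise for each gene sized from the difference between the 2 microRNA libraries. Of 200 genes altered 4-fold, 181 were recovered, and of 200 altered 2.5-fold, 128. For 1604 site genes lowered by 0.05 on the log2 scale, the site ranked number 1 among heptamers and the percentile was 0.00, and with no shift the rank was 8165 and the percentile 2.5, which lies at the threshold. Alternatives for the pseudocount, the FPKM filter, the unit, the scaling, the size rule, the site type and the random matching were computed for the results that each could apply to. Heptamer ranks had only the setting with limited log2 differences, the shared control only a pseudocount of 0.1 and an FPKM of at least 5, and single genes no FPKM filter. The data were read with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Levels of mature microRNAs were not analysed, and symbols carried by several identifiers were matched by identifier.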

Results

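Gene expression was measured by RNA sequencing in QBC-939, a human cholangiocarcinoma (bile duct cancer) cell line. The cells overexpressed miR-182-5p, miR-183-5p or a control that the labels call NC, with 1 library in each of the 3 groups. The sample titles of the 2 microRNA libraries end in "mim", and that of the NC library does not. The gene counts summed to 61709874 in the miR-182-5p library, 67427313 in the miR-183-5p library and 64516706 in the NC library. The 2 microRNAs come from the same gene cluster and have related but different seeds, the short 5' stretch with which a microRNA pairs with messenger RNAs. Levels of the microRNAs themselves were not analysed here, so the overexpression was not checked. With 1 library per group there is no replicate check: all values describe these 3 libraries, no p-value was computed between conditions, and the 95% intervals in parentheses after ratios of library-size-normalised counts (CPM) cover counting error only.

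An FPKM of at least 1 was reached by 12995 genes in the miR-182-5p library, 12621 in the miR-183-5p library and 12342 in the NC library. Mitochondrially encoded genes took 16.7% of the counts in the miR-182-5p library, 16.1% in the miR-183-5p library and 13.5% in the NC library. A larger mitochondrial share lowers the CPM of all nuclear genes alike, by -0.056 on the log2 scale for miR-182-5p against NC. The CPM ratios below are not corrected for this, so intervals just below or just above 1 are to be read with that shift in mind. Genes with no coding transcript took 5.18% (miR-182-5p), 4.73% (miR-183-5p) and 4.06% (NC). Transcripts of epithelial cells were present in all libraries: in the NC library the biliary keratin KRT19 had 229 CPM, the intestinal keratin KRT20 93.3 CPM, the microvillus protein VIL1 179.6 CPM and the gastric mucin MUC5AC 117 CPM, whereas the mesenchymal filament gene VIM had 3.70 CPM. Other intestinal genes differed in level: in the NC library GPX2 had 644 CPM, CEACAM5 40.2 CPM and LGR5 14.2 CPM, but the transcription factor CDX2 had 19 counts (0 in the miR-182-5p library) and the cadherin CDH17 had 0 (12 in the miR-182-5p library). Across 13454 genes with an FPKM of at least 1 in any library, 65.6% lay within 1.2-fold of NC in the miR-182-5p library and 85.6% in the miR-183-5p library. The correlation of log2 values across genes, which are not independent replicates, was 0.977 between the miR-182-5p and NC libraries, 0.987 between the miR-183-5p and NC libraries and 0.9845 between the microRNA libraries.

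The comparison of the miR-182-5p library with the NC library addressed which genes differ when miR-182-5p is overexpressed, and whether reported targets of this microRNA are among the lower genes. Genes of cholesterol synthesis and uptake, the interferon response, the hypoxia response and inflammatory NF-kB signalling were higher in the miR-182-5p library, and ribosomal protein and histone genes were lower. The sterol carrier STARD4 had 1.37 times the NC level (1.31 to 1.42), and the prostaglandin-degrading enzyme HPGD had 0.687 times the NC level (0.595 to 0.793). Reported miR-182-5p targets as a group were not lower: 11 of the 22 measured were higher and 7 were lower with intervals that exclude 1. A difference of at least 2-fold, computed as log2 of FPKM plus 1, separated 103 genes that were higher and 50 that were lower among 13267 measured genes; these numbers depend on the scale, with 596 and 280 genes after rescaling to TPM and 19 and 19 when limited to genes with FPKM of at least 5.

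HPGD (ENSG00000164120, chromosome 4, 174490175 to 174523065 in GRCh38) encodes 15-hydroxyprostaglandin dehydrogenase, which inactivates prostaglandin E2, and is a reported target of both microRNAs. It had 320 counts in the miR-182-5p library (5.19 CPM), 336 in the miR-183-5p library (4.98 CPM) and 487 in the NC library (7.55 CPM). Its 3' UTR of 1907 nucleotides holds 1 miR-182-5p seed site, TTGCCAA, at 174492077 to 174492083, which begins at nucleotide 1 after the stop codon, and 0 miR-183-5p sites of this kind. Of the genes of prostaglandin synthesis, breakdown and reception, 9 reached an FPKM of at least 1 in any library, none a receptor. HPGD reached it in the NC library alone, at 1.12 against 0.78 (miR-182-5p) and 0.75 (miR-183-5p). It thus lies near the filter and is included through the library where it is highest. Of these 9 genes, 6 were lower and 3 higher in the miR-182-5p library with intervals excluding 1. The lower ones included the cyclooxygenase PTGS1 at 0.880 times NC (0.839 to 0.923), the prostaglandin reductase PTGR1 at 0.793 (0.745 to 0.844), the synthases PTGES3 at 0.778 (0.764 to 0.792) and PTGES2 at 0.856 (0.823 to 0.889), and the phospholipase PLA2G4A at 0.877 (0.820 to 0.938). The reductase PTGR2 was higher at 1.24 (1.12 to 1.37), as were the thromboxane synthase TBXAS1 at 1.14 (1.10 to 1.19) and the exporter ABCC4 at 1.11 (1.06 to 1.16). The median log2 difference of the 9 genes was -0.15, at percentile 12.7 of 10000 random lists of the same size matched on expression. Members below this FPKM in all 3 libraries were left out. Among them the cyclooxygenase PTGS2, with an FPKM of 0.98 in the miR-182-5p library, was higher at 1.53 (1.31 to 1.80). So were, on fewer counts, PTGES at 1.69, AKR1B1 at 1.91, PTGDS at 1.96 and PTGER4 at 2.18. PTGER3 at 0.418 and PTGER1 at 0.750 had intervals that include 1.

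**Figure D1:**
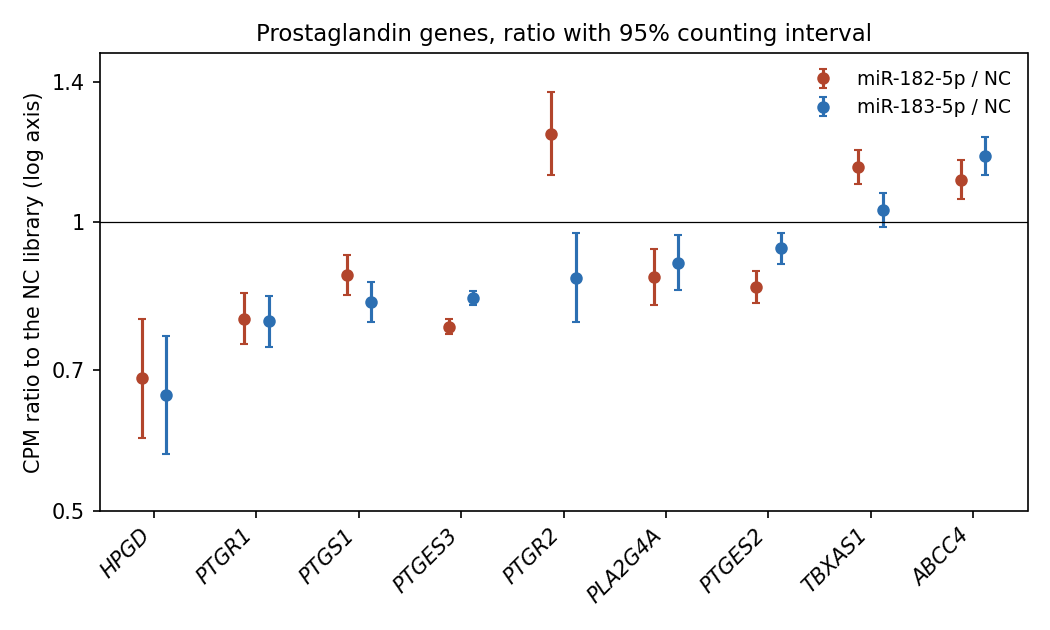
CPM ratio to the NC library on a log axis of each prostaglandin gene with an FPKM of at least 1 in any library. The miR-182-5p library is in red and the miR-183-5p library in blue. Bars are exact 95% counting intervals. Among these genes HPGD has the smallest ratio in both, at 0.687 and 0.660, but it reached that FPKM in the NC library alone.

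Among the reported miR-182-5p targets, the signal transducer SMAD4 was the highest at 1.38 times NC (1.28 to 1.498) and the autophagy receptor OPTN was at 1.37. The hypoxia-induced gene NDRG1 and the cytoskeletal gene MTSS1 were both at 1.27, the adenylate cyclase ADCY6 at 1.25, the growth factor receptor IGF1R at 1.196, the ubiquitin ligase adaptor FBXW7 at 1.19 and the deubiquitinase CYLD at 1.18. The cortactin gene CTTN and the matrix gene THBS1 were both at 1.07. Besides HPGD, the lower ones were the DNA repair gene BRCA1 at 0.852 (0.812 to 0.894), the transcription factor FOXO1 at 0.855 (0.774 to 0.945), the hypoxia factor EPAS1 at 0.889, the Ras regulator RASA1 at 0.898, the deubiquitinase USP15 at 0.918 and the NF-kB inhibitor TNIP1 at 0.939. FOXO3, with 2 miR-182-5p sites, was at 0.997 (0.943 to 1.05), and the intervals of CREB1, BCL2L12 and PDCD4 also included 1. The median of the 22 genes was 0.08 on the log2 scale, at percentile 80.7. Reported miR-183-5p targets had a median of -0.0034 in this library, at percentile 64.0, with the phosphatase subunit PPP2CA lowest of those not shared with the other list at 0.770 (0.748 to 0.793), then the scaffold gene AKAP12 at 0.803 and the kinesin KIF2A at 0.812.

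All 15 measured cholesterol genes had ratios above 1 in the miR-182-5p library, 13 of them with intervals above 1. Their median was 0.23, at percentile 99.98. Besides STARD4, the sterol sensor INSIG1 was at 1.31, and the smallest ratios were those of FDFT1 and IDI1, both at 1.01. Interferon response genes had a median of 0.22 (percentile 99.97), with IFI44 at 1.41 (1.31 to 1.51), the regulator IRF7 at 1.36 (1.23 to 1.51) and the chemokine CCL5 at 1.34, while ISG15 was at 0.967 with an interval that includes 1. Hypoxia response genes had a median of 0.31 (percentile 99.25), with the carbonic anhydrase CA9 at 1.41, the growth factor VEGFA at 1.32 and the kinase PDK1 at 1.37, but the hydroxylase EGLN3 at 0.895. NF-kB genes had a median of 0.24 (percentile 98.67), with the apoptosis inhibitor BIRC3 at 1.54 (1.43 to 1.65), the ubiquitin-editing enzyme TNFAIP3 at 1.44 and the chemokine CXCL1 at 1.43, but the inhibitor NFKBIA at 0.813 (0.766 to 0.864). The 13 mitochondrially encoded genes had a median of 0.25 (percentile 100), from MT-ATP8 at 0.893 to MT-CO2 at 1.38.

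Ribosomal protein genes were lower in the miR-182-5p library in 47 of 47 cases, from RPS12 at 0.657 (0.644 to 0.671) to RPS24 at 0.957 (0.943 to 0.971). Their median was -0.35 (percentile 0.00), where random lists of equally expressed genes had a median of -0.21, so highly expressed genes were lower in general. The 4 measured replication-dependent histone genes had a median of -0.40 (percentile 0.08, but 2.63 when the random lists were also matched on transcript length), with H1-2 at 0.649 (0.570 to 0.739). Cell cycle genes had a median of -0.23 (percentile 6.11, but below the 2.5th with CPM in place of FPKM): the replication clamp PCNA was at 0.709 (0.692 to 0.726), the mitotic activator CDC20 at 0.743 and the helicase subunit MCM2 at 0.754, whereas the proliferation antigen MKI67 was at 1.06 and CCNE2 at 1.24. Glycolysis genes had a median of -0.23 (percentile 25.1), with GAPDH at 0.716 and PGAM1 at 0.717 but the glucose transporter SLC2A1 at 1.05.

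Other groups lay inside both percentile thresholds in the miR-182-5p library. The median was 0.16 for FOXO-activated genes (percentile 97.1) and 0.15 for the microRNA machinery (96.2), and with CPM in place of FPKM both passed the upper threshold. It was 0.12 for Wnt feedback genes (94.1), 0.01 for unfolded protein and integrated stress genes (91.9), 0.03 for biliary epithelium markers (88.0), 0.06 for stemness and drug efflux genes (86.0), 0.12 for YAP and TAZ targets (84.3), 0.08 for immediate early genes (84.0), 0.13 for genes of the epithelial-mesenchymal transition (83.6), 0.11 for p53 targets (82.5) and 0.07 for TGF-beta-induced genes (71.9). Single members differed more than these medians. The stress-induced gene GADD45B was at 1.64 (1.30 to 2.07) and the sestrin SESN3 at 1.34, the argonaute genes AGO4 at 1.31 and AGO3 at 1.23, and the nuclear exporter XPO5 at 0.819. The pluripotency factor POU5F1 was at 1.70 (1.476 to 1.955), MYC at 0.827 (0.808 to 0.847), the stem cell marker PROM1 at 1.23 and CD44 at 1.198. The biliary enzyme GGT1 was at 1.64 (1.55 to 1.74), the mucin MUC1 at 1.51 and the chloride channel CFTR at 1.42, with KRT18 at 0.773. The junction gene OCLN was at 1.36, the p53 targets BTG2 and BBC3 both at 1.33, the chaperone SDF2L1 at 0.683, CHAC1 at 0.715, the TGF-beta regulator SKIL at 0.733 and RNF43 at 1.22. Too few members of the hepatocyte, fibroblast and immune or endothelial lists were measured for a median: the ratios to NC were 0.913 for HNF4A, 1.37 for SERPINA1, 1.86 for COL1A1 and 0.948 for LYZ. Of the genes named in this paragraph, XPO5, POU5F1, CD44, GGT1, CFTR, BBC3, RNF43 and HNF4A overlap another gene on the same strand, so their reads are not assigned with certainty. GGT1 lies largely within AP000356, which fell from 690 counts to 29, so part of the higher GGT1 ratio may come from reads counted for the other gene. The same overlap applies to the prostaglandin genes PTGS1, PTGES3 and PTGR2, to the targets SMAD4, ADCY6, IGF1R, CYLD, THBS1, BRCA1, USP15, PDCD4, PPP2CA and TAOK1, and to LGR5, SLC2A1, PFKFB4, FAS, CCNB2, RPS12 and MT-ATP8.

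**Figure D2:**
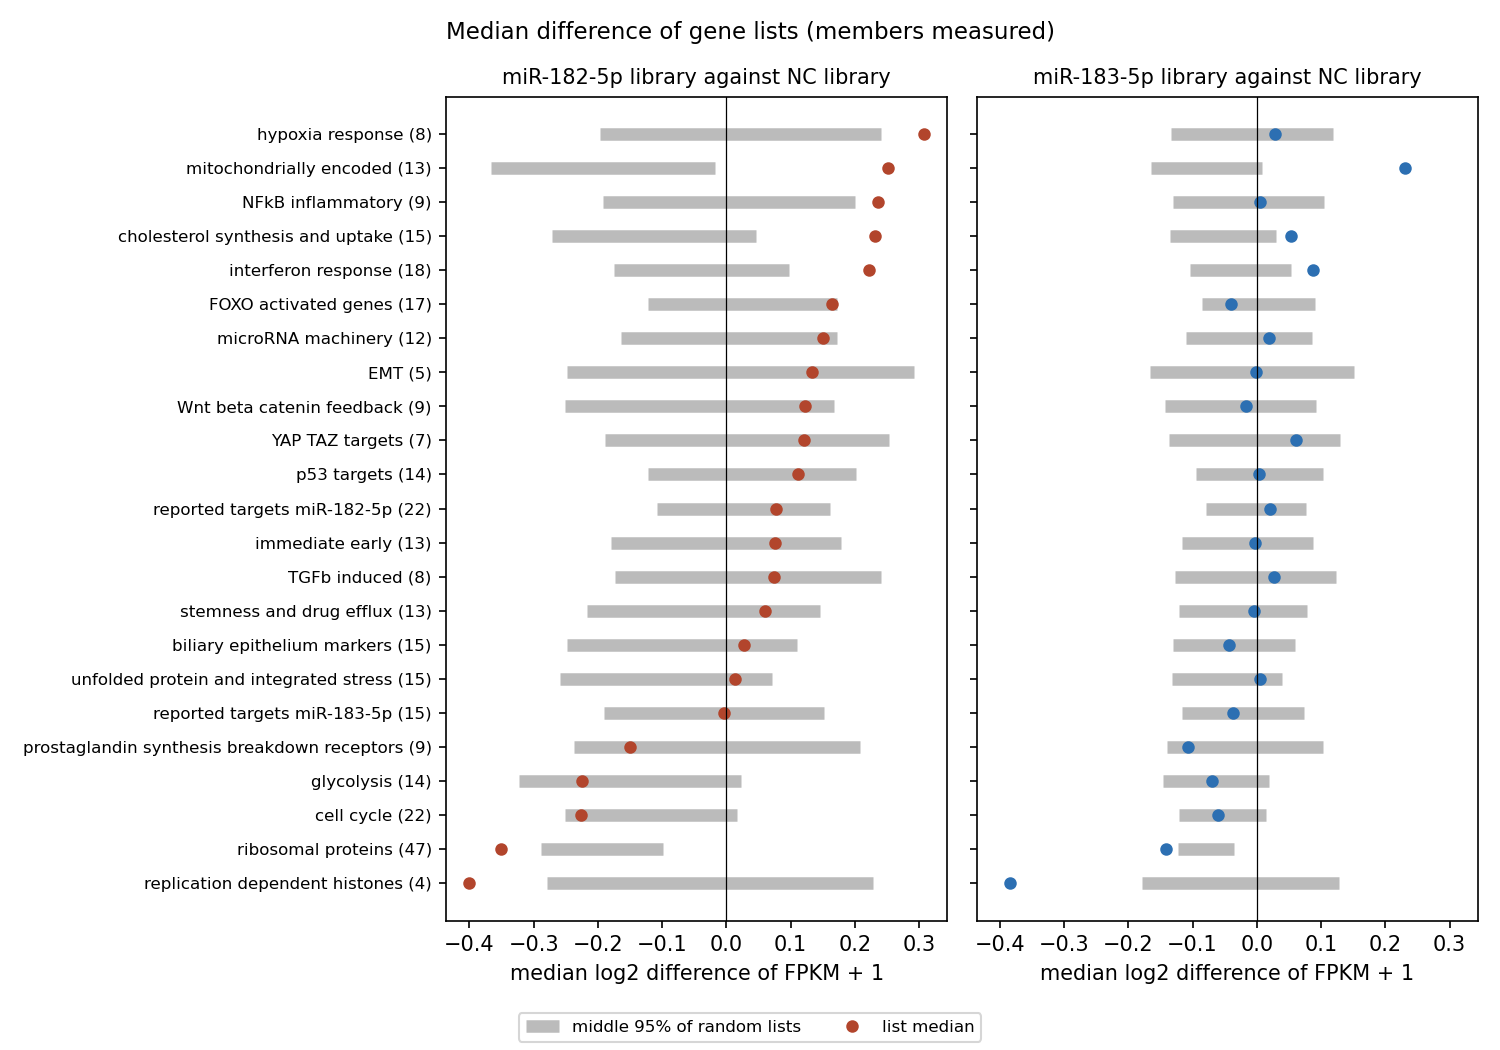
Median log2 difference from the NC library (FPKM plus 1) of each gene list on the x axis, with the miR-182-5p library on the left and the miR-183-5p library on the right; points are list medians and gray bars the middle 95% of random lists matched on expression. Hypoxia genes have a median of 0.31 on the left and 0.03 on the right, and histone genes -0.40 and -0.38.

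The largest differences named by the fixed rule were mostly at overlapping genes: 11 of the 12 lower and 11 of the 12 higher ones overlap another gene on the same strand, where reads cannot be assigned to a single gene with certainty. The read-through gene ISY1-RAB43 had 0 counts against 1588 in NC (at least 506-fold lower), and MIR34AHG, the host transcript of miR-34a, 0 against 614 (at least 196-fold lower). Also lower were AC023055, AL133352, AC004922, BOLA2, AC010132, AP000356, AL355385, AC000120 and AL137782, from 0.0128 times NC in BOLA2 to 0.133 in AL137782 among those with counts. The exception without overlap on its strand was TSPOAP1-AS1 (ENSG00000265148), an antisense transcript, at 0.0212 (0.0153 to 0.0286). On the higher side, LHFPL5 (ENSG00000197753), a component of the hair cell mechanotransduction channel, had no overlap on its strand and stood at 26.1 times NC (20.2 to 34.4). Whether the counts were strand-specific is not known, and on the opposite strand LHFPL5 overlaps SRPK1 (171 CPM in NC) and TSPOAP1-AS1 overlaps RNF43 (426 CPM), so these are uncertain too. The cilium gene CCDC39 (ENSG00000145075) had 739 counts against 0 in NC (at least 257.5-fold higher), and the read-through genes PPAN-P2RY11 and HSPE1-MOB4 were at least 171-fold and 158-fold higher. POC1B-GALNT4 was at 8.04 and the Rac regulator CHN2 at 14.3, and the others were AL445685, AL136295 (ENSG00000254692), AC005726, FP565260 (ENSG00000276612), AC016026 and AC245060 (ENSG00000272779). Of the genes past 2-fold, 37 higher and 16 lower ones overlap no other gene on their strand.

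The following genes without overlap on their strand were chosen after their values were seen. The cornified envelope gene SPRR1B was at 0.175 times NC (0.133 to 0.228), the actin regulator FGD4 at 0.384 (0.353 to 0.417), the assembly factor COX20 at 0.383, and the liver transcription factor CEBPA at 0.491 (0.429 to 0.562). The aldo-keto reductases AKR1C1 at 0.458 (0.442 to 0.474) and AKR1C3 at 0.501 and the aldehyde dehydrogenase ALDH3A1 at 0.490 (0.446 to 0.539) were also lower; the aldo-keto reductases have near-identical family members that can share reads. Higher were the calcium-binding gene CABP1 at 3.45, the phosphatase PTPRO at 3.12, the hypoxia-induced NDUFA4L2 at 3.20 (2.58 to 3.995) and the chloride channel BEST1 at 2.93 (2.65 to 3.24). Of these, COX20, CABP1, NDUFA4L2 and BEST1 overlap genes on the opposite strand, BEST1 the ferritin gene FTH1, which had 2411 CPM in NC against 8.29 for BEST1.

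Genes with a miR-182-5p seed site in the 3' UTR were slightly lower in the miR-182-5p library than matched genes, but this depended on how sites and genes were chosen. The 1604 genes with a site had a median log2 difference of -0.0066, which was higher by 0.031 than that of 6682 genes without one, but lower by 0.015 than that of random lists matched on expression and 3' UTR length (minus random -0.015, percentile 0.03). The percentile was 10.2 with 8mer sites alone, 7.19 in the shortest 3' UTRs, 3.04 with a mean FPKM of at least 5 and 59.4 with at least 2 sites, where the median lay above that of random lists by 0.0034. Genes with miR-183-5p sites were at percentile 9.07, with miR-96-5p sites at 63.0, with miR-16-5p sites at 95.5, with miR-21-5p sites at 99.83 and with let-7 sites at 100. Ranked by the mean difference of the genes that hold it, the miR-182-5p site was number 745 of 16159 heptamers. With log2 differences limited to plus or minus 1 it was number 1297. In a simulated library with a shift of -0.05 the site was number 1. There each gene varied independently, so that rank is not directly comparable with the rank in the data. The 10 lowest site genes were NME1-NME2 at 0.245, AC093512 at 0.355, AKR1C1, the ribosomal gene RPS29 at 0.597, the calcium-binding gene CALB2 at 0.639, DOHH at 0.642, MRM2 at 0.647, COTL1 at 0.662, the prohibitin gene PHB at 0.664 and the quinone reductase NQO1 at 0.677 (0.664 to 0.690). Of these, NME1-NME2, AC093512, RPS29 and MRM2 overlap another gene on the same strand, so their reads are not assigned with certainty.

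**Figure D3:**
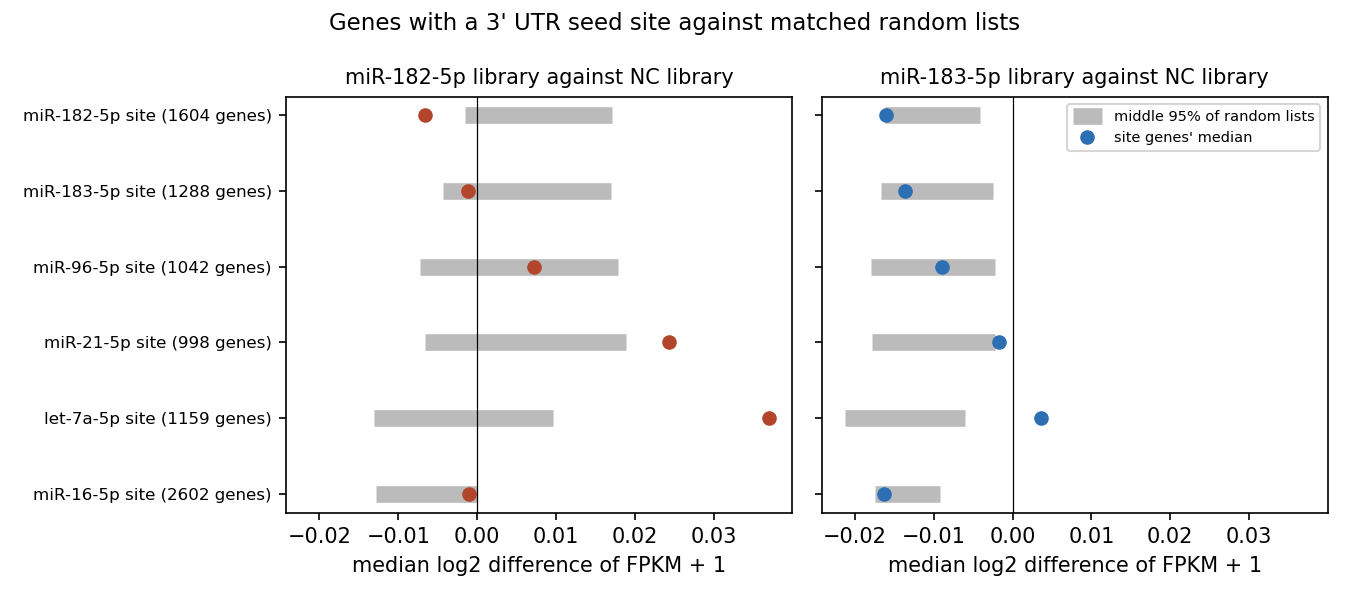
Median log2 difference from the NC library (FPKM plus 1) of genes with a 3' UTR seed site of each microRNA on the x axis, with the miR-182-5p library on the left and the miR-183-5p library on the right; points are medians and gray bars the middle 95% of random lists matched on expression and 3' UTR length. The miR-182-5p sites lie left of their bar in the miR-182-5p library at -0.0066, and let-7 sites lie right of theirs in both, at 0.037 and 0.0036.

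The comparison of the miR-183-5p library with the NC library addressed the same questions for miR-183-5p. HPGD was lower here too, at 0.660 times NC (0.573 to 0.760). Both HPGD ratios rest on the same NC value of 487 counts, so this is not an independent repeat. A high HPGD value in the NC library cannot be told apart from an effect of the microRNAs. Of the 15 measured reported miR-183-5p targets, 7 were lower with intervals below 1 against 3 that were higher. Their median lay among random lists. In the miR-182-5p library 7 of the 15 were lower as well, against 6 that were higher, so lower targets were not particular to the miR-183-5p library. These numbers are not corrected for the larger mitochondrial share, which lowers all nuclear ratios. Histone and ribosomal protein genes were lower and interferon response genes higher, with smaller ribosomal protein differences than in the miR-182-5p library, whereas hypoxia and NF-kB genes lay among random lists. A difference of at least 2-fold separated 60 higher and 36 lower genes among 12926 measured genes, with 371 and 284 after rescaling to TPM and 12 and 14 when limited to genes with FPKM of at least 5.

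Among the reported miR-183-5p targets, FOXO1 was at 0.803 times NC (0.728 to 0.887), KIF2A at 0.894 (0.864 to 0.925), the translation inhibitor PDCD4 at 0.909 (0.865 to 0.956), the membrane linker EZR at 0.912 (0.889 to 0.935), PPP2CA at 0.924 and AKAP12, with 3 sites, at 0.957 (0.921 to 0.995). The ubiquitin ligase subunit BTRC was at 1.17 (1.09 to 1.25), SMAD4 at 1.15 (1.06 to 1.25) and the integrin ITGB1 at 1.02. PPP2CB, LRP6, EGR1, TAOK1 and IDH2 had intervals that include 1. The median was -0.037, at percentile 38.8. Reported miR-182-5p targets had a median of 0.02 (percentile 70.7), with NDRG1 at 0.885 (0.847 to 0.924) and OPTN at 1.23 (1.14 to 1.32). Of the 9 measured prostaglandin genes 7 were lower and 1 higher, with a median of -0.11 at percentile 7.77 (below the 2.5th with a pseudocount of 0.1). PTGR1 was at 0.787 (0.741 to 0.837), PTGS1 at 0.825 (0.787 to 0.866), PTGES3 at 0.833, PTGR2 at 0.875, PLA2G4A at 0.907 and PTGES2 at 0.938, while ABCC4 was at 1.17 (1.12 to 1.23) and TBXAS1 at 1.03. Among the members left out by the FPKM filter, PTGS2 was higher at 1.43 (1.22 to 1.68). On fewer counts AKR1B1 was at 1.67, PTGDS at 1.71 and PTGER4 at 1.99, whereas PTGES was lower at 0.494 (0.252 to 0.931).

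The 4 histone genes had a median of -0.38 in the miR-183-5p library (percentile 0.01), with H1-2 at 0.624 (0.549 to 0.709) and H2AC6 at 0.688. Ribosomal protein genes had a median of -0.14 (percentile 0.18, random lists -0.082), with RPS12 lowest at 0.783 (0.768 to 0.798) and RPS24 at 0.997. Interferon response genes had a median of 0.09 (percentile 99.73), with OAS2 at 1.28 (1.21 to 1.36), CXCL10 at 1.195 and IFI44 at 1.19. Cholesterol genes had a median of 0.05 (percentile 99.17, but inside the threshold with CPM), although FDFT1 was lower, at 0.939 (0.912 to 0.966). Mitochondrially encoded genes had a median of 0.23 (percentile 100), with MT-CO2 at 1.35 and MT-ATP8 at 0.884.

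Hypoxia genes had a median of 0.03 (percentile 75.0) in the miR-183-5p library, with PDK1 at 1.22 and the glycolytic regulator PFKFB4 at 0.797 (0.708 to 0.896), and NF-kB genes one of 0.0046 (60.0), with BIRC3 at 1.23, NFKBIA at 0.683 and CXCL1 at 0.650 (0.541 to 0.779). FOXO-activated genes had a median of -0.040 (18.9), with GADD45B at 1.58 and the cyclin CCNG2 at 0.812. The median of cell cycle genes was -0.060 (47.5), with CCNE1 at 0.726 (0.675 to 0.779), PCNA at 0.844 and MKI67 at 1.07. For the remaining groups it was -0.070 for glycolysis (52.3), 0.02 for the microRNA machinery (74.5), -0.018 for Wnt feedback genes (58.4), 0.0048 for stress genes (89.8), -0.043 for biliary markers (50.95), -0.0042 for stemness genes (68.2), 0.06 for YAP and TAZ targets (84.1), -0.0034 for immediate early genes (60.8), -0.0010 for genes of the epithelial-mesenchymal transition (57.3), 0.0038 for p53 targets (52.9) and 0.03 for TGF-beta-induced genes (69.9). Members far from these medians were POU5F1 at 1.52, MYC at 0.839, the drug exporter ABCG2 at 0.809, the death receptor FAS at 1.41 (1.27 to 1.57), the matricellular gene CCN2 at 0.676 (0.550 to 0.830), the water channel AQP1 at 0.743, CHAC1 at 0.752 and the matrix gene FN1 at 1.201. Across the 3 comparisons, 6 of 69 list medians lay below percentile 2.5 and 15 above the upper threshold.

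Of the largest differences named by the fixed rule in the miR-183-5p library, all 12 lower and 10 of the 12 higher ones were at overlapping genes. Lower were ISY1-RAB43 with 0 counts (at least 553-fold), RPL17-C18orf32 with 0 against 542 (at least 189-fold), ZNF358 with 0 against 445 (at least 155-fold), UTP14C at 0.0758, PTGES3L-AARSD1 at 0.124, AL358113 at 0.0347, AP000356, AL133352, AC131160, AC010132, AC242842 (ENSG00000286185) and AP001267. The higher genes without overlap on their strand were LHFPL5 at 21.8 times NC (16.8 to 28.7) and the histamine receptor HRH1 (ENSG00000196639) at 20.6 (13.9 to 31.8). The others were CCDC39 with 578 counts against 0 (at least 184-fold), RAB4B-EGLN2 at 35.1, AL591806, AL445685, AC011511 (ENSG00000267303), FP565260, AC016026, AC010323, AC087721 and AC005192. Of the genes past 2-fold, 17 higher and 8 lower ones overlap no other gene on their strand. Chosen after their values were seen and without overlap on their strand, the F-box gene FBXO41 was at 0.360 (0.344 to 0.376), the kinase regulator SH3BP5 at 0.448 (0.392 to 0.510), BEST1 at 0.490 (0.422 to 0.568), ALDH3A1 at 0.515 and AKR1C1 at 0.535 (0.518 to 0.553), with the kinase MAST4 at 2.02 and the mannose isomerase MPI at 1.88 (1.79 to 1.98) on the higher side. HRH1, SH3BP5, BEST1, MAST4 and MPI overlap genes on the opposite strand.

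Against NC, genes with miR-183-5p sites as a whole lay among matched random lists in the miR-183-5p library, whereas those with 8mer sites or with several sites were lower. The 1288 site genes had a median of -0.014, and their difference from matched random lists was -0.0043 (percentile 16.1). With 8mer sites alone, in 241 genes, the difference was -0.022 (percentile 0.77), and with at least 2 sites, in 153 genes, it was -0.031 (percentile 0.16). Between the microRNA libraries the 241 genes with 8mer sites lay among matched random lists (difference 0.0066, percentile 68.2). Genes with miR-182-5p sites were at percentile 2.90 and with let-7 sites at percentile 100 in this library. The miR-183-5p site ranked number 132 of 16159 heptamers here and number 320 in the miR-182-5p library. The 10 lowest site genes were the liver transcription factor FOXA3 at 0.614 (0.553 to 0.681), RPS29 at 0.687, the GTPase RHOU at 0.722, PTS at 0.727, the glutathione synthesis gene GCLM at 0.730 (0.691 to 0.771), NANS and MFSD11 both at 0.743, the glucuronosyltransferase UGT1A6 at 0.759, MOB4 at 0.765 and PPP1R14B at 0.773. Of these, RPS29, MFSD11, UGT1A6, MOB4 and PPP1R14B overlap another gene on the same strand.

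The comparison of the miR-182-5p library with the miR-183-5p library asked where the microRNAs differ, independently of the NC library. Hypoxia, NF-kB, cholesterol and interferon genes were higher in the miR-182-5p library, and cell cycle and ribosomal protein genes lower. HPGD did not differ detectably at this depth, at a ratio of 1.04 (0.890 to 1.22). PFKFB4 was 2.10 times and CXCL1 2.21 times as high in the miR-182-5p library. A difference of at least 2-fold separated 63 higher and 46 lower genes among 13308 measured genes, with 430 and 265 after rescaling to TPM and 13 and 15 when limited to genes with FPKM of at least 5.

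Between the microRNA libraries, hypoxia genes had a median of 0.24 (percentile 99.66), NF-kB genes 0.23 (99.81), cholesterol genes 0.10 (99.84), interferon genes 0.12 (99.74) and mitochondrially encoded genes 0.07 (99.95). FOXO-activated genes had a median of 0.15 (99.12) and p53 targets 0.14 (97.9), both inside the threshold when limited to genes with FPKM of at least 5. Cell cycle genes had a median of -0.19 (percentile 0.09), with CDC20 at 0.832, PCNA at 0.839 and the mitotic cyclin CCNB2 at 0.824, and ribosomal protein genes -0.20 (0.04). Histone genes were at 0.09 (86.7), prostaglandin genes at 0.0082 (56.8), and the reported targets of miR-182-5p at 0.05 (74.0) and of miR-183-5p at 0.02 (71.0). MUC1 was 1.502 times, CCN2 1.65 times and CCNG2 1.46 times as high in the miR-182-5p library. Genes with miR-182-5p sites were below matched random lists by a similar margin as against NC (minus random -0.016, percentile 0.00), but at percentile 39.0 with at least 2 sites, and genes with miR-183-5p sites were at percentile 51.5.

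The largest differences between the microRNA libraries were also mostly at overlapping genes, 5 of 6 on the lower and 6 of 6 on the higher side. Lower in the miR-182-5p library were TSPOAP1-AS1 at 0.0208 (0.0150 to 0.0281, no overlap on its strand), MIR34AHG with 0 counts against 854 (at least 260.5-fold), AC004922, AC011511, AC087721 and AP001273 (ENSG00000284057). Higher were POC1B-GALNT4 at 14.2, HSPE1-MOB4 with 454 counts against 0 (at least 165-fold), AL358113 at 26.9, AL136295, AC005726 and AP002748 (ENSG00000256349). Chosen after their values were seen, genes without overlap on their strand included HRH1 at 0.0468 (0.0298 to 0.0704) and FGD4 at 0.397 on the lower side, and BEST1 at 5.98 (5.26 to 6.83), the sulfate transporter SLC13A4 at 7.57 and FBXO41 at 3.31 (3.16 to 3.45) on the higher side. Of these, HRH1, BEST1 and SLC13A4 overlap genes on the opposite strand.

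The differences of both microRNA libraries from NC were related, which arises at least in part because the same NC library stands in both. Across 13454 genes the correlation of the differences was 0.621, against 0.4999 in 100 simulations in which the libraries shared nothing but the control and all 3 had equal spread. The data depart from that assumption. The SD of the log2 differences was 0.3285 for miR-182-5p against NC, 0.2421 for miR-183-5p against NC and 0.2603 between the microRNAs. The correlation follows from these 3 SDs alone, so libraries of unequal spread that share nothing but NC can give the same value. The distance from the simulations therefore does not show an effect common to the microRNAs. The same caution applies to the following numbers of genes. In both libraries 24 genes were at least 2-fold higher and 16 at least 2-fold lower, where the simulations gave 4.32 and 3.76. The numbers depended on the setting: with a pseudocount of 0.1 there were 156 and 52 genes against 81.9 and 79.2 simulated, so that fewer genes were lower in both than simulated, and with FPKM of at least 5 there were 7 and 6 against 3.77 and 3.81. LHFPL5 and CCDC39 were among the genes higher in both, and ISY1-RAB43 and the ribosomal pseudogene RPL7AP6 among those lower in both.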

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

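Tests chosen only after the data had been seen were those with CPM (for single genes, with FPKM), with same-strand overlapping genes summed, with length-matched random lists, without mitochondrially encoded genes and with limited log2 differences. Of 417 list medians under alternatives, 403 kept their direction and their side of the threshold, 9 newly passed it and 5 no longer did; centring and leaving out mitochondrial genes moved none across it, which they could hardly do since each changes all nuclear genes alike. Of 42 values of seed-site genes 34 were the same. Numbers of genes past 2-fold were within 1.5 times in 17 of 54 cases, among them all after centring and the 6 without the FPKM filter, which could not change since a 2-fold difference with a pseudocount of 1 needs an FPKM of at least 1. The correlation of both differences from NC was the same in 2 of 2 settings, but the number of genes lower in both against the simulations was not: 52 against 79.2 simulated with a pseudocount of 0.1, and 6 against 3.81 with an FPKM of at least 5. Of 2016 values of single genes, 1859 moved by less than 1.5-fold.

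Numbers of genes (higher and lower, for miR-182-5p against NC, miR-183-5p against NC, and miR-182-5p against miR-183-5p) were 446 and 117, 209 and 120, 248 and 122 with a pseudocount of 0.1; 237 and 80, 113 and 67, 134 and 79 with 0.5; and 596 and 280, 371 and 284, 430 and 265 after rescaling to TPM. They were 640 and 205, 231 and 145, 307 and 125 with a 1.5-fold rule. With an FPKM of at least 5 they were 19 and 19, 12 and 14, 13 and 15, because fewer genes remain. With CPM, 174 genes were higher for miR-182-5p and 55 lower for miR-183-5p. With overlapping genes summed and CPM in place of FPKM, 16 were lower for miR-182-5p, 14 higher and 10 lower for miR-183-5p, and 38 higher and 14 lower between the microRNAs. A smaller pseudocount or fold admits more genes by construction, as does TPM, which raises every value against a pseudocount of 1; for the other numbers the cause was not tested.

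For miR-182-5p site genes in the miR-182-5p library, the difference from genes without a site was 0.043 with a mean FPKM of at least 5, 0.035 with 8mers and 0.012 with the shortest 3' UTR, no longer past the threshold against matched lists. It was 0.065 with at least 2 sites, where the direction against matched lists was reversed (0.0034, percentile 59.4). Between the microRNAs it was 0.037 with at least 2 sites, no longer past the threshold (percentile 39.0). In the miR-183-5p library, miR-182-5p sites with a pseudocount of 0.1 newly passed the threshold against matched lists (-0.0092, percentile 0.14; 0.0070 from genes without a site). So did miR-183-5p sites with 8mers (-0.022; -0.0071 from genes without a site) and with at least 2 sites (-0.031; -0.0090). The miR-183-5p heptamer in the miR-182-5p library ranked 413 with limited differences, and the miR-182-5p heptamer moved from 745 to 1297. With CPM, medians newly past the threshold were -0.25 for cell cycle, 0.21 for FOXO-activated and 0.17 for microRNA machinery genes in the miR-182-5p library and 0.16 for Wnt genes between the microRNAs, while cholesterol genes in the miR-183-5p library, at 0.033, no longer were. With a pseudocount of 0.1, 0.22 for FOXO-activated genes (miR-182-5p) and -0.16 for prostaglandin genes (miR-183-5p) newly passed, and 0.18 for p53 targets between the microRNAs no longer did. With an FPKM of at least 5, stress genes (miR-183-5p) at 0.056 and biliary markers between the microRNAs at 0.067 newly passed, and FOXO-activated genes at 0.13 and p53 targets at 0.14 no longer did. With length matching, FOXO-activated genes at 0.16 newly passed and histones at -0.40 no longer did (miR-182-5p). For the site, heptamer and list results the cause was not tested. No paired analysis was possible because each group has 1 library, and counting error alone limits the zero counts to a floor of 3.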

Other observations

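All tests of the NRF2-regulated genes and the test of the mitochondrial share were chosen only after the result was seen. Genes of the antioxidant and detoxification response regulated by NRF2, a transcription factor activated by oxidative stress, were lower in both microRNA libraries. The iron storage genes FTH1 and FTL were at 0.564 and 0.5795 times NC in the miR-182-5p library and at 0.749 and 0.778 in the miR-183-5p library. The retinal reductase AKR1B10 was at 0.545 and 0.6265, the glutathione peroxidase GPX2 at 0.649 and 0.776, the transaldolase TALDO1 at 0.663 and 0.827, the sulfiredoxin SRXN1 at 0.669 and 0.923, the peroxiredoxin PRDX1 at 0.685 and 0.813 and the thioredoxin reductase TXNRD1 at 0.717 and 0.845. SRXN1 and TXNRD1 overlap another gene on the same strand, so their reads are not assigned with certainty. Of 29 measured members 27 were lower with intervals below 1 in the miR-182-5p library and 25 in the miR-183-5p library. The exporter ABCC3 was the exception on the higher side in both, at 1.42 in the miR-182-5p library and 1.12 in the miR-183-5p library.

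The list of these genes was written after 7 members had been seen among the low genes, so the pattern was tested on the 22 measured members whose values had not been seen. Their median log2 difference was -0.41 in the miR-182-5p library, which is -0.3131 from that of expression-matched random lists, and -0.22 in the miR-183-5p library, both at percentile 0.00. Weaker recovery of short transcripts alone would not give this, since against lists also matched on length the distance was still -0.2923 (percentile 0.00). Reads shared with near-identical copies of aldo-keto reductase and ferritin genes do not account for it either, since without these genes it was -0.2401 (percentile 0.04 for miR-182-5p and 0.00 for miR-183-5p). Lower NRF2 activity in both microRNA cultures is therefore a hypothesis that may be tested with NRF2 protein levels. Between the microRNA libraries, a difference that NC does not enter, the unseen members had a median of -0.18 (percentile 0.17). Without the aldo-keto reductase and ferritin genes the median was -0.12 (percentile 4.66), inside the threshold. Whether the microRNAs, the shared NC library or culture conditions are behind the lower levels against NC stays open, because each group has a single library.

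Ribosomal protein genes were lower in the miR-182-5p library in 47 of 47 cases, with a median of -0.35. Equally expressed genes were also lower, with a median of -0.21 in random lists, so comparisons with random lists concern the part beyond this general difference. The share of counts in genes with no coding transcript was 5.18% in this library and 4.06% in NC, and whether RNA composition or library preparation differed was not tested. Short transcripts alone could not account for the part beyond the general difference. Among random lists matched on expression and length the median was at percentile 0.03. Median relative lengths were 0.633 for the list and 0.646 for the matched lists. The larger mitochondrial share lowers all nuclear genes by the same factor, -0.056 on the log2 scale, so it cannot bear on that part. It is also too small for the whole difference from NC. With mitochondrially encoded genes left out of the totals the median of the list was still -0.2965 (middle 50% of the members -0.33 to -0.23), with 46 of 47 genes below 0. The sizes of the median and of the factor fixed this outcome in advance. A culture or growth difference between the libraries cannot be separated from the microRNA with 1 library per group, and no other biological explanation was tested.

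Genes with 2-fold differences overlapped another gene on the same strand more often than measured genes in general. On the CPM scale, 234 genes differed at least 2-fold between the miR-182-5p and NC libraries, and 58.55% of them overlap another gene on the same strand, against 27.2% of all measured genes (Fisher's exact test, two-sided, p = 5.8e-24, across genes). Both genes of an overlapping pair can be counted and are not independent, so the Fisher p-values across genes here may be too small. A candidate explanation for the larger share is that reads were assigned to one or the other of overlapping genes differently from library to library. When the counts of overlapping genes were summed, 90.51% of the 137 overlapping genes fell below 2-fold, but this sum also dilutes a real difference: with the partners held constant 82.5% already did. The partners differed in the opposite direction in 58.39% of cases (exact 95% interval 49.67 to 66.75), against 44.6% for other overlapping genes (Fisher's exact p = 0.0016). In the miR-183-5p library this share was 75.2% (66.0 to 83.0). Direct action of the microRNA cannot be told apart from chance here: 4 of the 14 genes at least 2-fold lower with a searched 3' UTR hold a miR-182-5p site (28.57%, against 15.2% of all, Fisher's exact p = 0.251), which is too few to decide. Real changes between transcripts of these loci and an assignment of reads both remain open, since the counting method is not stated.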
